A study of Mus musculus with 4 samples.

How the data were processed

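The data are 4 RNA-seq libraries of polyA RNA from NK cells of mouse liver, 2 of TRAIL+ and 2 of CD49b+ cells, taken by flow sorting after density separation and red cell lysis, per the labels' protocols. Groups and replicate numbers came from the sample titles. The deposited values are RPKM, reads scaled to gene length and library size, per the file headers. Reads were aligned with TopHat 1.4.1 to build mm9, per the submitters' processing notes. The counting tool, the annotation version, any filter and the use of strand are not given in the sources used here, so overlapping and antisense genes cannot be told apart. Each file held 21025 rows in the same order, each with a gene symbol and its RefSeq accessions.

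Gene names were matched to RefSeq genes of GRCm38.p6, a later build than the authors' mm9, so no coordinates are given. Of the rows, 20661 were matched by accession, 191 by symbol and 65 by synonym, and 108 kept the name in the file. Some rows pool the accessions of related genes. Zfp683 and some other listed genes had no matching row and were not analysed here.

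RPKM is not a count, but its low values move in whole steps. For each row a gene length was found for which the values in all libraries are whole reads within a relative tolerance of 1e-06, and this held for 100% of the 13681 rows above 0. In a check, 2000 of 2000 rows drawn at random were whole, and 0 of 2000 after each library was multiplied by a random factor. Of 10439 rows with 1 accession and an annotated length, 81.1% had a length within 10% of the annotated one, so reads of the other rows are less certain. The reads of a library ranged from 3786497 to 4232967, and the 10 most abundant genes took 5.51% to 7.56% of reads. Reads summed over genes were higher than the reads behind the RPKM, at 4015891 to 4491481. Rows may share reads, or the lengths worked out for some rows may be too large, and the sums do not tell these apart. Intervals and floors cover counting error only.

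Genes with RPKM of at least 1 in at least 2 of the 4 libraries were tested (10047 genes) on log2(RPKM + 1) with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with a trended prior. The model had the subset as its term, coded TRAIL+ minus CD49b+, and 2 residual degrees of freedom with a prior of 3.51. Genes past a Benjamini-Hochberg adjusted p of 0.05 are called changed. Log2 fold changes are given ± SE on the log2(RPKM + 1) scale, which understates the change of low genes. Folds without a log are ratios of group means of RPKM, larger over smaller, and mean ± SD is over 2 libraries. Counts of genes past a fold threshold are the exception and use the log2(RPKM + 1) scale. With 2 against 2 the smallest exact permutation p is 0.333, so single-gene permutation tests were not used. Where a group had 1 to 3 reads the ratio of reads per total is given with its exact binomial 95% interval, and where it had 0 reads, a bound against a floor of 3 reads over the group.

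Before the data were examined, the design, the rule for the genes named, the alternatives and 31 gene lists were fixed. The lists cover the sort gate, liver-resident and type 1 innate lymphoid cells, mature NK cells, transcription factors, Ly49 and other NK receptors, cytotoxic effectors, cytokines, cytokine receptors, trafficking receptors, integrins, TNF family and inhibitory receptors, interferon response, TGF-beta response, cell cycle, immediate-early genes, ribosomal proteins, oxidative phosphorylation, glycolysis, cholesterol synthesis and long non-coding RNAs. The others hold markers of T cells, B cells, other innate lymphoid cells, Kupffer cells and monocytes, neutrophils, dendritic cells, hepatocytes, endothelial and stellate cells, erythroid cells and platelets, mast cells and basophils, and sex-linked genes. Lists with at least 3 tested genes (27) were compared with all other genes by camera with a preset correlation of 0.01, adjusted over the lists. Members were also counted, over all genes and adjusted over the list alone. The rule for the genes named took the gate genes; Nfil3 and 12 other transcription factors, with up to 4 further called factors a direction; the 12 largest changes in each direction among called genes with groups that did not overlap; up to 4 called members of each list by size of change and up to 2 of the opposite direction; and the 2 most abundant members of each list of other cell types. Any other gene is said to be named after its value was seen. Of the genes this rule took, 2 are not reported here.

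The tests were run on simulated reads drawn with the means and library sizes of these libraries, with 200 genes changed. Changed genes were drawn only from those above a minimum of reads. All genes had the same dispersion (0.0248), taken from abundant genes, and libraries were drawn independently. The recoveries therefore do not describe low genes. In 9943 genes of this simulated comparison, 99% of genes changed 4-fold and 40% of genes changed 2-fold were recovered, and 10 of 9718 unchanged genes were called. The alternatives of the fixed plan were other pseudocounts (0.1 and 0.5 RPKM), filters, scalings between libraries, variance priors and an adjusted p of 0.01, a block for the replicate number, each library left out in turn, camera with an estimated correlation, and fry. Added after seeing the data were voom on the recovered reads and a gene length correction, a lowess fit of each library's deviation on log2 gene length. The planned count models were not run, since the deposited values are RPKM and not counts, and voom on the recovered reads was run instead. Figures were drawn with matplotlib 3.10.9, and other steps used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.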

Results

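RNA was sequenced from natural killer (NK) cells sorted from the livers of C57BL/6 mice, in 4 libraries. TRAIL+ cells (2 libraries) carried the death ligand TRAIL and no CD49b on their surface, and CD49b+ cells (2 libraries) carried CD49b and no TRAIL. Both were negative for the T-cell receptor beta chain and positive for NK1.1 and NKp46. The series title places the comparison in a study of how NK cell development depends on Nfil3, a bZIP transcription factor, and the files used here compare the sorted subsets. Reads per library, worked out from the steps of the RPKM values, were 4071617 and 3786497 for TRAIL+ replicates 1 and 2, and 4232967 and 3933014 for CD49b+ replicates 1 and 2. At these depths 1 RPKM in a gene of 2000 bases stood for 7.57 to 8.47 reads. Where a call was lost without a CD49b+ library, adjusted p-values without CD49b+ replicate 1 and without CD49b+ replicate 2 are given in that order. A range after a fold is that with 1 library left out, given where the fold moved by over 1.5 times. The labels do not say that the replicates came from separate mice, so p-values measure the spread between these libraries, which may be technical.

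The genes behind the sort gates were examined to check the labels and are not findings. Tnfsf10, which encodes TRAIL, stood at 199 ± 13.2 RPKM in TRAIL+ cells and 7.10 ± 0.226 in CD49b+ cells (SD, n = 2 each), a log2 fold change of 4.62 ± 0.16 (SE, limma adjusted p = 0.000301). Itga2, which encodes CD49b, stood at 3.41 ± 2.62 and 44.5 ± 10.7 RPKM, a log2 fold change of -3.49 ± 0.45 (limma adjusted p = 0.00914). The genes of the shared gate did not pass the test. Klrb1c (NK1.1) had a log2 fold change of -0.11 ± 0.27 and Ncr1 (NKp46) of -0.03 ± 0.23, at group means of 1042 to 1148 RPKM. As a list, the 4 gate genes had 1 member higher and 1 lower, both over all genes and adjusted over the list alone, and the list test (camera) gave an adjusted p of 0.866.

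TRAIL+ cells expressed Cd3g, the chemokine receptor gene Cxcr6, granzyme C (Gzmc) and the Cd200r1 and Cd200r2 receptors at levels over 100 times those of CD49b+ cells. CD49b+ cells in turn held nearly all of the mast cell protease transcript Cma1, the Ly49 receptor transcript Klra4 and the T-box factor Eomes. Of 10047 genes tested, 866 differed between the subsets, 478 higher and 388 lower in TRAIL+ cells (limma on log2(RPKM + 1), adjusted p threshold 0.05, n = 2 per group). At least 2-fold differences on the log2(RPKM + 1) scale were seen in 426 and 354 of these, and at least 8-fold differences in 67 and 60. Counts by fold below use the same scale, which leaves out some low genes with larger ratios of means. All 866 had groups that did not overlap, against 46.8% of tested genes and 33.3% by chance for 2 against 2. A call with so few libraries nearly requires this, so it is no separate support. The counts were 777 higher and 763 lower without TRAIL+ replicate 1, 245 and 198 without CD49b+ replicate 1, and 256 and 211 without CD49b+ replicate 2. At 2-fold, the lower count was 586 without TRAIL+ replicate 1, and every gene called without a CD49b+ library was at least 2-fold different, so those counts stayed at 245 and 198 and at 256 and 211. A correction for gene length, chosen after seeing the data, gave 716 and 596.

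**Figure D1:**
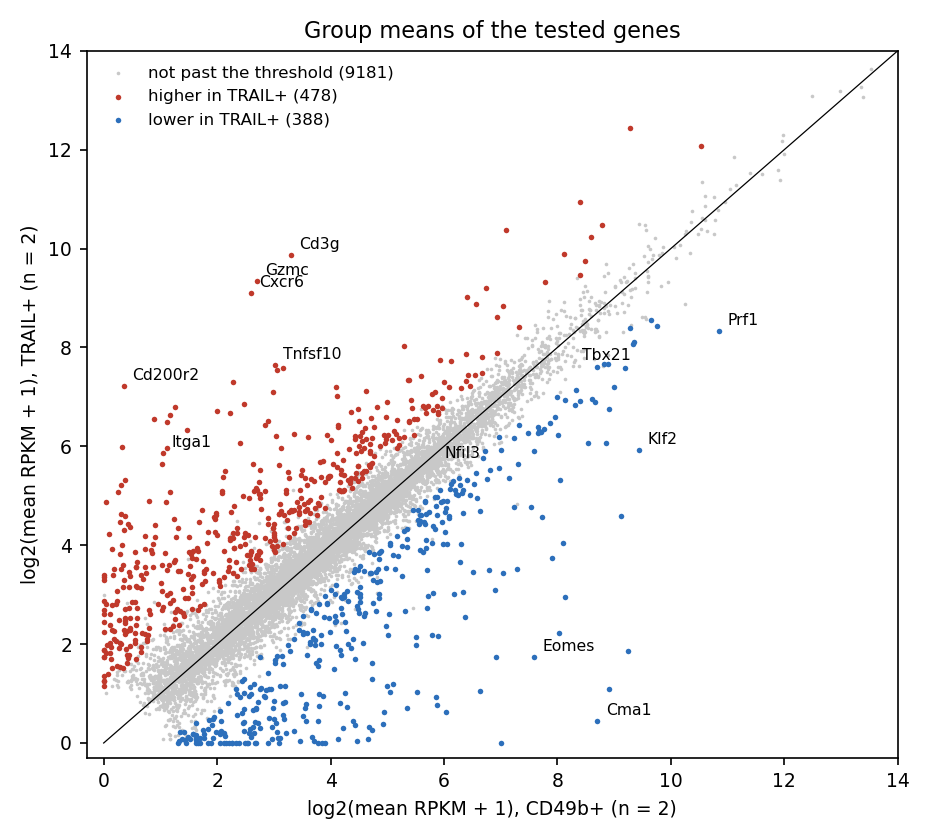
Mean RPKM of each tested gene in CD49b+ cells (horizontal) against TRAIL+ cells (vertical), each as log2(mean + 1) over 2 libraries; the line marks equal values. Red points are the 478 genes higher and blue points the 388 genes lower in TRAIL+ cells at an adjusted p below 0.05, and 12 genes are labelled.

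Among the genes with the largest positive fold changes, Cd200r2 stood at 148 ± 5.03 RPKM in TRAIL+ and 0.279 ± 0.0145 in CD49b+ cells (log2 fold change 6.86 ± 0.17, SE). Its CD49b+ level rested on 4 reads, a ratio of reads of 531 with an exact 95% counting interval of 207 to 1952. Gzmc followed at 650 ± 77.8 and 5.52 ± 1.76 RPKM (6.66 ± 0.24), then Cd3g, a subunit of the CD3 complex, at 936 ± 176 and 8.88 ± 3.15 (6.59 ± 0.27). Cxcr6 stood at 548 ± 182 and 5.06 ± 0.628 RPKM. The others of the 12 largest were the gelatinase gene Mmp9 (79.0-fold, 40.7 to 1361), Tmem273, Cd200r1 (110-fold), the ADP-ribosyltransferase gene Art2b (79.8-fold, 52.2 to 170), Osgin1 (75.9-fold), Asb2 (40.7-fold), the metalloprotease gene Adam19 (131-fold, 75.7 to 492) and the cadherin gene Cdh17 (150-fold, 107 to 249). Tmem273 had 3 reads over the CD49b+ libraries, and its ratio of reads was 252 with an exact 95% counting interval of 86.0 to 1227. Limma adjusted p ranged over these 12 genes from 0.000231 for Cd200r2 to 0.00372 for Mmp9. The Cd200r genes form a family of close copies, so reads may be shared among them.

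Among the genes with the largest negative fold changes, Cma1 stood at 0.358 ± 0.185 RPKM in TRAIL+ and 417 ± 22.4 in CD49b+ cells. It rested on 3 reads over the TRAIL+ libraries, a ratio of 1176 with an exact 95% counting interval of 402 to 5703. Serpinb9b, a granzyme inhibitor family gene, had 0 reads in both TRAIL+ libraries and 4010 in the CD49b+ libraries. Against a floor of 3 reads over the group it was at least 1283-fold lower in TRAIL+ cells. Klra4 was 423-fold lower (285 to 818). Also in this group were Eomes, the sphingosine phosphate receptor gene S1pr5 (71.7-fold), the arsenic methyltransferase gene As3mt (90.5-fold), Cx3cr1 (122-fold, 75.9 to 306), Klrg1 (41.7-fold), the chemerin receptor gene Cmklr1 (50.9-fold), Rap1gap2 (81.7-fold) and Mcam (62.2-fold). Limma adjusted p over the genes named here ranged from 0.000231 for Cma1 to 0.000797 for Klrg1.

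Eomes and Zeb2 led the transcription factors that fell in TRAIL+ cells, and Id3 those that rose. Of 39 tested, 3 rose and 9 fell (5 and 12 adjusted over the list alone), and 27, among them Nfil3, did not pass the test. Without TRAIL+ replicate 1, 5 rose and 14 fell. Eomes stood at 2.34 ± 0.507 RPKM in TRAIL+ and 192 ± 10.2 in CD49b+ cells (SD, n = 2 each), a log2 fold change of -5.86 ± 0.18 (limma adjusted p = 0.000301). Nfil3 stood at 48.8 ± 8.33 and 57.4 ± 5.96 RPKM. Its log2 fold change was -0.24 ± 0.19, with a 95% interval of -0.71 to 0.24 (limma adjusted p = 0.627), which leaves differences inside that interval open. Zeb2, a repressor that acts in NK cell maturation, had a log2 fold change of -4.38 ± 0.25, Klf2 of -3.60 ± 0.36, Irf8 of -2.78 ± 0.17 and Tcf7 of -1.79 ± 0.15, and all 4 fell. Prdm1, which encodes Blimp-1, fell by 1.32 on the log2 scale, a call lost without either CD49b+ library (adjusted p = 0.135 and 0.100025). Id3 (2.87 ± 0.29), the aryl hydrocarbon receptor gene Ahr (2.34 ± 0.20) and Tox (1.78 ± 0.20) were higher in TRAIL+ cells.

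Tbx21, which encodes T-bet, stood at 196 ± 0.929 RPKM in TRAIL+ and 310 ± 23.3 in CD49b+ cells, and its log2 fold change of -0.66 ± 0.17 missed the threshold (limma adjusted p = 0.0843). It passed after the gene length correction (adjusted p = 0.01002). Id2, Gata3, Zbtb16, Hhex and Rora had adjusted p-values of 0.431 to 0.897 and log2 fold changes of 0.44, 0.13, -0.40, -0.07 and 0.56. Zfp683 was not analysed here. The list of transcription factors as a whole was lower in TRAIL+ cells (camera adjusted p = 0.00392), with an adjusted p = 0.867 with an estimated correlation and 0.0724 without TRAIL+ replicate 2.

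**Figure D2:**
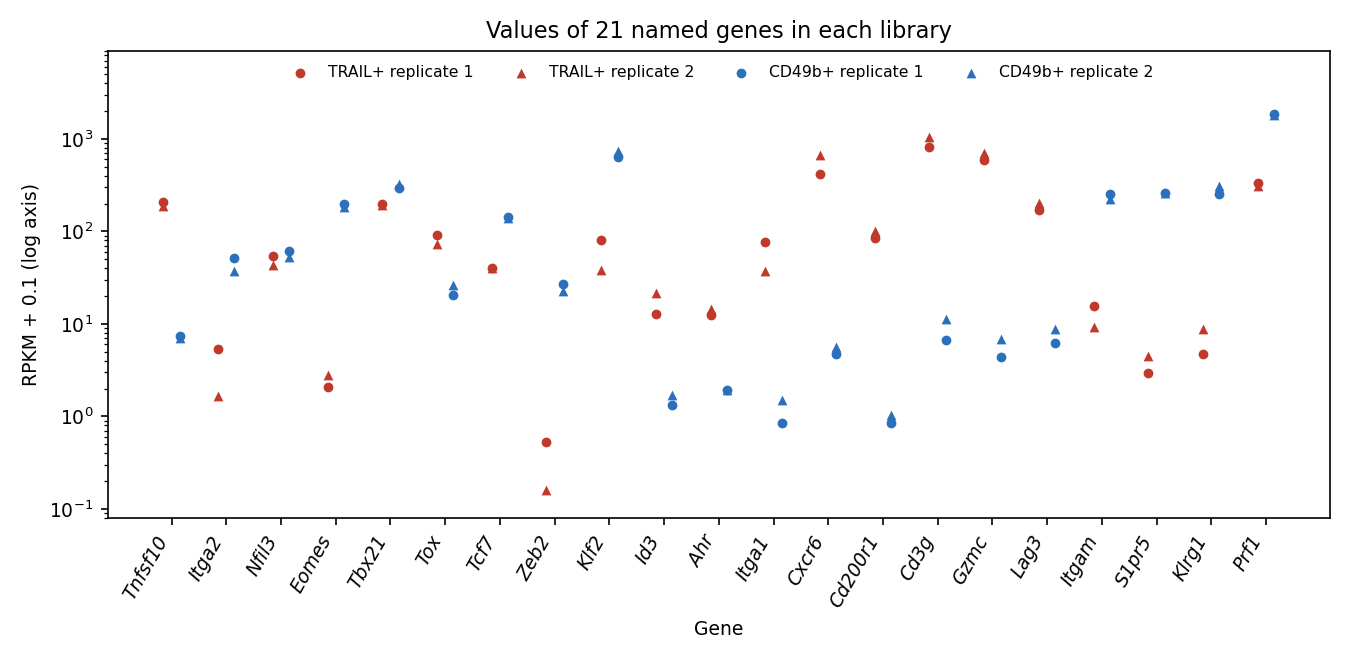
RPKM + 0.1 on a log axis for 21 named genes, with a point per library (circles, replicate 1; triangles, replicate 2; red, TRAIL+; blue, CD49b+). Nfil3 lies between 42.9 and 61.6 RPKM in the 4 libraries, while Eomes lies at 1.98 and 2.70 in TRAIL+ and at 199 and 184 in CD49b+ libraries.

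Genes linked to liver-resident and type 1 innate lymphoid cells were mostly higher in TRAIL+ cells, and genes of circulating mature NK cells were mostly lower. Of 23 tested genes of the resident list, 15 rose and 3 fell (17 and 4 adjusted over the list alone), with a median log2 fold change of 2.63. Cd3g, Cxcr6, Cd200r1 and Asb2 led the list, and Itga1, the collagen-binding integrin CD49a, stood at 57.0 ± 27.8 RPKM against 1.07 ± 0.459. Socs3, Ctla2a and Sdc4 went the other way, by -2.11, -1.71 and -1.07 on the log2 scale. The Socs3 call was lost without CD49b+ replicate 1 (adjusted p = 0.0977), and those of Ctla2a (0.0522 and 0.0826) and Sdc4 (0.202 and 0.314) without either CD49b+ library. Sdc4 was named after its value was seen. For the list as a whole, camera gave an adjusted p = 7.68e-12, and adjusted p = 0.408 with an estimated correlation.

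Of 23 tested genes of the mature NK list, 21 fell and 0 rose, over all genes and adjusted over the list alone. The median log2 fold change was -3.60, also with Cma1 at its ratio of reads. Cma1, Klra4 and Eomes were among its leading members. Camera gave the list an adjusted p = 5.50e-29, and adjusted p = 0.166 with an estimated correlation. Both lists were drawn from general knowledge of these subsets, which rests on cells sorted in similar ways. Of the 27 lists tested, 0 passed camera with an estimated correlation, which rests on 2 residual degrees of freedom, and 3 had an unadjusted p under 0.05.

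NK receptors of the Ly49 and related families moved both ways, with 5 of 28 tested members higher and 9 lower in TRAIL+ cells (8 and 11 adjusted over the list alone, list adjusted p = 0.253). Klra4, Klrg1 and Klra7 (17.8-fold, 12.8 to 29.1) were lower, whereas Klra5 was 23.9-fold higher, Lilrb4a 5.54-fold and the adhesion receptor gene Cd226 3.94-fold. Slamf7 (2.43-fold) and Cd96 (2.01-fold), named after their values were seen, were the other higher members, and lost their calls without either CD49b+ library (adjusted p = 0.124 and 0.116, and 0.212 and 0.2503). Without either CD49b+ library, 3 members were higher and 7 lower, and after the gene length correction 8 and 11. Without TRAIL+ replicate 2 or CD49b+ replicate 1 the list was lower (adjusted p = 0.0179 and 0.0261). Ly49 genes are near-identical copies that can share reads, so single members are uncertain.

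Cytotoxic effector genes split by member. Perforin (Prf1) stood at 320 ± 16.7 RPKM in TRAIL+ and 1837 ± 49.7 in CD49b+ cells, a 5.75-fold difference (log2 fold change -2.52 ± 0.20, limma adjusted p = 0.00235). Gzmm and the granzyme B inhibitor gene Serpinb9 also fell (6.52-fold, 4.76 to 10.3, and 3.46-fold), as did Gzmk (-2.68 ± 0.54) and the syntaxin gene Stx11 (-1.06 ± 0.16). The Gzmk call was lost without CD49b+ replicate 2 (adjusted p = 0.0707) and with voom on the recovered reads (0.0805), among others, and that of Stx11 without either CD49b+ library (0.238 and 0.132). In contrast, Gzmc was 118-fold higher in TRAIL+ cells. Gzmb, named after its value was seen, was 2.92-fold higher and lost its call without either CD49b+ library (0.778 and 0.537). Over the 20 tested members, 2 were higher and 7 lower (3 and 7 adjusted over the list alone), and the list test gave an adjusted p of 0.0787. The counts were 4 and 7 without TRAIL+ replicate 1, 1 and 4 without CD49b+ replicate 1, 1 and 3 without CD49b+ replicate 2, and 4 and 8 after the gene length correction. It passed as lower without TRAIL+ replicate 2 (0.0168) or CD49b+ replicate 1 (0.0342). Granzymes C to G lie among close copies, so reads can be shared.

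Secreted factors also divided the subsets. Il2 had 85 reads in the TRAIL+ libraries and 0 in both CD49b+ libraries, at least 29.5-fold higher against a floor of 3 reads over the group. Csf1, the macrophage growth factor, was 29.5-fold higher (19.6 to 59.3) and the chemokine Xcl1 5.88-fold higher (1971 ± 547 against 335 ± 7.62 RPKM). Osm (6.15-fold), Ccl9 (27.5-fold, 16.7 to 77.8) and Tgfb3 (5.11-fold) were lower. The call of Xcl1 was lost without either CD49b+ library (adjusted p = 0.0693 and 0.0714) and that of Tgfb3 without CD49b+ replicate 1 (0.0611). Ltb (5.52-fold) and Csf2 (2.84-fold), both higher, were named after their values were seen, and the Csf2 call was lost without either CD49b+ library (0.228 and 0.121) and with voom (0.0643). Of 18 tested cytokine genes 5 rose and 3 fell (8 and 3 adjusted over the list alone, list adjusted p = 0.239), and 3 and 3 without CD49b+ replicate 2.

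Among 22 cytokine receptor genes tested, 7 rose and 4 fell (10 and 6 adjusted over the list alone, list adjusted p = 0.253), and without either CD49b+ library 2 rose and 2 fell. The IL-18 receptor subunit genes Il18r1 and Il18rap were 10.7-fold and 6.77-fold lower in TRAIL+ cells. The higher members named next are in order of change on the log2(RPKM + 1) scale. Il21r was 7.89-fold and Tgfbr1 3.40-fold higher, followed by Il2ra (3.81-fold) and Il12rb1 (2.70-fold), whose calls were lost without either CD49b+ library (adjusted p = 0.0684 and 0.139 for Il2ra, 0.0579 and 0.0888 for Il12rb1). Ifngr1 (3.05-fold) and Il10ra (2.45-fold), named after their values were seen, were the other lower members, and lost their calls likewise (0.0658 and 0.107, and 0.0606 and 0.135). The median of this list was 0.44, and fry, which asks if genes move on balance in 1 direction, gave an adjusted p of 0.0317.

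Receptors of cell migration moved both ways. S1pr5, Cx3cr1 and Cmklr1 were lower in TRAIL+ cells, and Cxcr6, the leukotriene receptor gene Ltb4r1 and Cxcr3 were higher. Cxcr3 stood at 519 ± 121 against 83.6 ± 22.1 RPKM, and Ltb4r1, with 3 reads in CD49b+ cells, had a ratio of 42.0 (exact 95% counting interval 14.0 to 207). The other higher members, named after their values were seen, were Ccr8, with 40 reads in TRAIL+ and 0 in CD49b+ cells (at least 13.9-fold), and Ptger4 (2.17-fold), whose call was lost without either CD49b+ library (adjusted p = 0.113 and 0.258). Of 18 tested, 5 rose and 8 fell (5 and 9 adjusted over the list alone). Camera gave the list an adjusted p of 0.122, and 0.0372 and 0.0376 without CD49b+ replicates 1 and 2, 0.0136 with the RPKM minimum at 5, and fry 0.00990.

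Integrin genes divided likewise, with 5 of 15 tested members higher and 6 lower (7 and 7 adjusted over the list alone, list adjusted p = 0.646), and 2 and 3 without either CD49b+ library. The lower members include the gate gene Itga2 in each count. Itgam (CD11b) was 19.3-fold and Itga4 9.20-fold lower in TRAIL+ cells, and Itga1 was 53.2-fold higher (34.9 to 76.4). Itga6 and Itga5 were 3.31-fold and 2.97-fold lower, calls that were lost without either CD49b+ library (adjusted p = 0.176 and 0.107, and 0.136 and 0.112). Higher were also Itgax and, named after their values were seen, Itgad (6.81-fold), Itgav (2.55-fold) and Itgb3 (2.52-fold). The last 2 lost their calls without either CD49b+ library (0.312 and 0.122, and 0.207 and 0.107), as did Itgax (0.335 and 0.297), and Itgav also without TRAIL+ replicate 2 (0.0619) and after the gene length correction (0.0780).

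Of 18 tested genes of the TNF superfamily and of inhibitory receptors, 7 rose in TRAIL+ cells, the gate gene Tnfsf10 among them, 0 fell and 11 did not pass (13 and 0 adjusted over the list alone). Without TRAIL+ replicate 1, 13 rose, and 12 after the gene length correction. Lag3, an inhibitory receptor, stood at 187 ± 24.4 against 7.36 ± 1.76 RPKM (log2 fold change 4.50 ± 0.21, limma adjusted p = 0.000583), and Tnfsf8 was 24.8-fold higher. Cd200r1 was another leading member. The list as a whole was higher, camera adjusted p = 2.92e-10, and adjusted p = 0.647 with an estimated correlation. Both tests include the gate gene Tnfsf10, so part of this shift was set by the sort.

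Interferon-induced genes rose in 7 of 27 tested members and fell in 0 (10 and 1 adjusted over the list alone). Isg20 was 5.82-fold, Oas3 3.48-fold, Isg15 2.94-fold and Rtp4 2.90-fold higher. The calls of Isg15 and Rtp4 were lost without either CD49b+ library (adjusted p = 0.0888 and 0.0647, and 0.0765 and 0.0631), as were those of Ifit1 (0.122 and 0.114), Ifit3 (0.341 and 0.146) and Gbp2 (0.140 and 0.179), named after their values were seen. Either way, 2 genes stayed higher, Isg20 and Oas3. Over the list, camera gave an adjusted p = 4.85e-05, and adjusted p = 0.408 with an estimated correlation, and the median log2 fold change was 0.39.

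Of 14 tested genes of the TGF-beta response list, 4 rose and 3 fell (5 and 4 adjusted over the list alone, list adjusted p = 0.866), and 2 and 1 without CD49b+ replicate 1, and 3 and 1 without CD49b+ replicate 2. Itga1, Tgfbr1 and the co-receptor gene Eng (log2 fold change 1.64 ± 0.24) were higher, as was Nt5e (2.27-fold), named after its value was seen. Rgs16, Tgif1 (-1.60 ± 0.22) and Cd9 (-1.44 ± 0.26) were lower. Rgs16 had 3 reads in TRAIL+ cells, a ratio of 44.8 (exact 95% counting interval 15.0 to 220). The calls of Tgif1, Cd9 and Nt5e were lost without either CD49b+ library (adjusted p = 0.0747 and 0.0734, 0.0656 and 0.162, and 0.438 and 0.209), that of Nt5e also without TRAIL+ replicate 1 (0.0568), and that of Eng without CD49b+ replicate 1 (0.0656). The list's median, -0.10, and mean, 0.24, differed in sign.

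Few genes of proliferation and core metabolism passed the threshold. In the lists of 29 cell cycle, 38 ribosomal protein and 32 oxidative phosphorylation genes, 0 genes passed with limma, with voom, or adjusted over the list alone, and 0, 1 and 0 had an unadjusted p under 0.05. The list tests gave adjusted p-values of 0.660, 0.866 and 0.660. Without TRAIL+ replicate 1 the cell cycle list was lower (adjusted p = 0.00680, 1 gene lower) and the ribosomal (0.000230, 4 genes higher) and oxidative phosphorylation (0.00680, 2 genes higher) lists were higher. Without TRAIL+ replicate 2 the ribosomal list was instead lower (0.000725), and 2 oxidative phosphorylation genes were lower. Ribosomal protein genes summed to 10060 and 17820 RPKM in TRAIL+ replicates 1 and 2, and to 11476 and 13986 in the CD49b+ replicates. Of 21 glycolysis genes, 1 rose and 2 fell, over all genes and adjusted over the list alone (list adjusted p = 0.605), and 4 fell without TRAIL+ replicate 2. Without TRAIL+ replicate 1, or after the gene length correction, 2 rose. Ldhb, a lactate dehydrogenase subunit, was 17.0-fold higher in TRAIL+ cells, whereas the lactate transporter gene Slc16a1 was 6.22-fold and Pfkp 3.31-fold lower. Of 13 long non-coding RNAs tested, 0 passed with limma or adjusted over the list alone, 2 had an unadjusted p under 0.05 and 1 passed with voom (list adjusted p = 0.646). Without TRAIL+ replicate 1, 1 passed, and 2 passed without TRAIL+ replicate 2 or after the gene length correction.

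In the cholesterol list, 3 of 20 genes rose and 1 fell, over all genes and adjusted over the list alone. The counts were 8 and 2 without TRAIL+ replicate 1, and 1 and 0 without either CD49b+ library. Lss, a sterol synthesis enzyme, was 4.68-fold higher in TRAIL+ cells. The regulator gene Srebf2 (2.10-fold higher) and the opposite Scd2 (2.13-fold lower) lost their calls without either CD49b+ library (adjusted p = 0.158 and 0.210, and 0.120 and 0.347), and Scd2 also after the gene length correction (0.0725). Camera gave the list an adjusted p = 0.0483, and adjusted p = 0.897 with an estimated correlation. It was 0.222 without TRAIL+ replicate 2, 0.0754 without CD49b+ replicate 1, 0.0718 after quantile normalization, 0.0544 after the gene length correction and 0.248 with the RPKM minimum at 5.

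The immediate-early list, which responds to cell handling and stimulation, had 1 of 28 genes higher (Gadd45b, 2.34-fold) and 1 lower (Nr4a2, 3.66-fold, 2.71 to 5.63), over all genes and adjusted over the list alone. Both calls were lost without either CD49b+ library (adjusted p = 0.119 and 0.121, and 0.123 and 0.0950). Without TRAIL+ replicate 1, 20 genes were lower, and without TRAIL+ replicate 2, 3. The list as a whole was lower in TRAIL+ cells, adjusted p = 0.0178, and adjusted p = 0.897 with an estimated correlation. It was 0.814 without TRAIL+ replicate 2, 0.0754 without CD49b+ replicate 1 and 0.0581 after quantile normalization. The list summed to 7263 and 3346 RPKM in TRAIL+ replicates 1 and 2 and to 7648 and 6514 in the CD49b+ replicates.

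Of 14 T-cell genes tested, 9 rose and 2 fell in TRAIL+ cells (11 and 2 adjusted over the list alone, median log2 fold change 1.67), although both sorts excluded cells with the T-cell receptor beta chain. Without CD49b+ replicate 1, 6 rose and 0 fell, and without CD49b+ replicate 2, 5 and 0. Cd3d lost its call without either (adjusted p = 0.0507 and 0.0566), as did Zap70 (0.381 and 0.308), Camk4 without CD49b+ replicate 1 (0.0901), and Cd4 (0.0648) and Trat1 (0.0777) without CD49b+ replicate 2, all 5 named after their values were seen. After Cd3g, the leading members were Cd8a, Cd3e at 32.2 ± 15.5 against 3.25 ± 0.888 RPKM and Bcl11b (8.79-fold). Cd8a, with 3 reads in CD49b+ cells, had a ratio of 120 (exact 95% counting interval 40.9 to 587). Cd28 and Cd247 were 2.93-fold and 2.25-fold lower, calls that were lost without either CD49b+ library (adjusted p = 0.0580 and 0.145, and 0.126 and 0.164). Thy1, the other abundant member, had an adjusted p of 0.397. Over the list, camera gave an adjusted p = 5.80e-06, and adjusted p = 0.647 with an estimated correlation.

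Markers of other liver and blood cells were examined because a sort can carry them along. In the dendritic cell list 2 of 7 tested genes rose and 0 fell (3 and 0 adjusted over the list alone). Itgax (CD11c), which NK cells also express, was 2.13-fold higher and lost its call without either CD49b+ library (adjusted p = 0.335 and 0.297). Xcr1, with 3 reads in CD49b+ cells, had a ratio of 37.5 (exact 95% counting interval 12.5 to 185), and Cd74 had an adjusted p of 0.819. The list test gave an adjusted p = 0.0163, and adjusted p = 0.647 with an estimated correlation. It was 0.156 without TRAIL+ replicate 1, 0.222 without CD49b+ replicate 2, where the list's median was -0.03 and the test stayed in the higher direction, 0.132 with no filter and 0.0817 with the RPKM minimum at 5.

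In the neutrophil (4 tested), hepatocyte (8 tested) and erythroid and platelet (3 tested) lists, 1 gene each passed, over all genes and adjusted over the list alone. These were Mmp9 and the transferrin gene Trf (4.16-fold), both higher, and the platelet gene Gp1bb, lower, whose 1 read in TRAIL+ cells gave a ratio of 270 (exact 95% counting interval 48.0 to 10694). Their list tests gave adjusted p-values of 0.253, 0.463 and 0.318. The lists of 9 B-cell and 9 Kupffer cell and monocyte genes had 0 genes past the limma threshold or with voom (0 and 1 adjusted over the list alone, and 1 each at an unadjusted p under 0.05), with list adjusted p-values of 0.974 and 0.253. In the Kupffer list 2 genes were higher without TRAIL+ replicate 1, 1 without TRAIL+ replicate 2 and 2 without CD49b+ replicate 1. The most abundant B-cell genes, Cd79b and Cd79a, had group means of 4.05 to 11.2 RPKM. Without CD49b+ replicate 1 the Kupffer (1.66e-05), neutrophil (1.67e-05) and hepatocyte (0.000744) lists were higher in TRAIL+ cells, and without CD49b+ replicate 2 the erythroid and platelet list was lower (0.00506).

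Several abundant markers differed more between replicates than between subsets. Lyz2 stood at 81.9 and 9.21 RPKM in TRAIL+ replicates 1 and 2, and at 122 and 8.87 in CD49b+ replicates 1 and 2. Alb stood at 12.7 and 1.92, and at 14.8 and 0.865. The Hbb-b2 row, which pools the accessions of adult beta globin copies, stood at 92.3 and 31.7, and at 102 and 5.22. S100a9 stood at 14.0 and 3.23, and at 14.9 and 0. Hbb-b2 and S100a9 passed as higher without CD49b+ replicate 1 (adjusted p = 0.0189 and 0.0491). Cd68 had an adjusted p of 0.321. The median and the direction of the list test differed in sign for the gate, TGF-beta response, glycolysis, B-cell, hepatocyte, and erythroid and platelet lists.

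Lists with fewer than 3 tested genes were not tested as lists. Of 2 endothelial and stellate genes tested, Fcgr2b, an inhibitory Fc receptor that NK cells and B cells can express, was 26.1-fold lower in TRAIL+ cells (16.3 to 65.7, log2 fold change -4.00 ± 0.36), and Pecam1 had an adjusted p of 0.739. Of the genes of other innate lymphoid cells, Kit (6.97 ± 1.64 against 12.1 ± 0.563 RPKM, adjusted p = 0.131) and Arg1 (adjusted p = 0.647) were tested and did not pass over all genes, and Kit passed as lower adjusted over the list alone and without TRAIL+ replicate 2 (0.0409). The mast cell and basophil gene Cpa3 had an adjusted p of 0.954, and Mcpt8 stayed under the minimum, with group means of 1.05 and 0.140 RPKM. The sex-linked list held 1 tested gene, Xist, at 5.43 to 6.75 RPKM in the 4 libraries, and 4 Y-linked genes stayed at or below 0.445 RPKM.

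**Figure D3:**
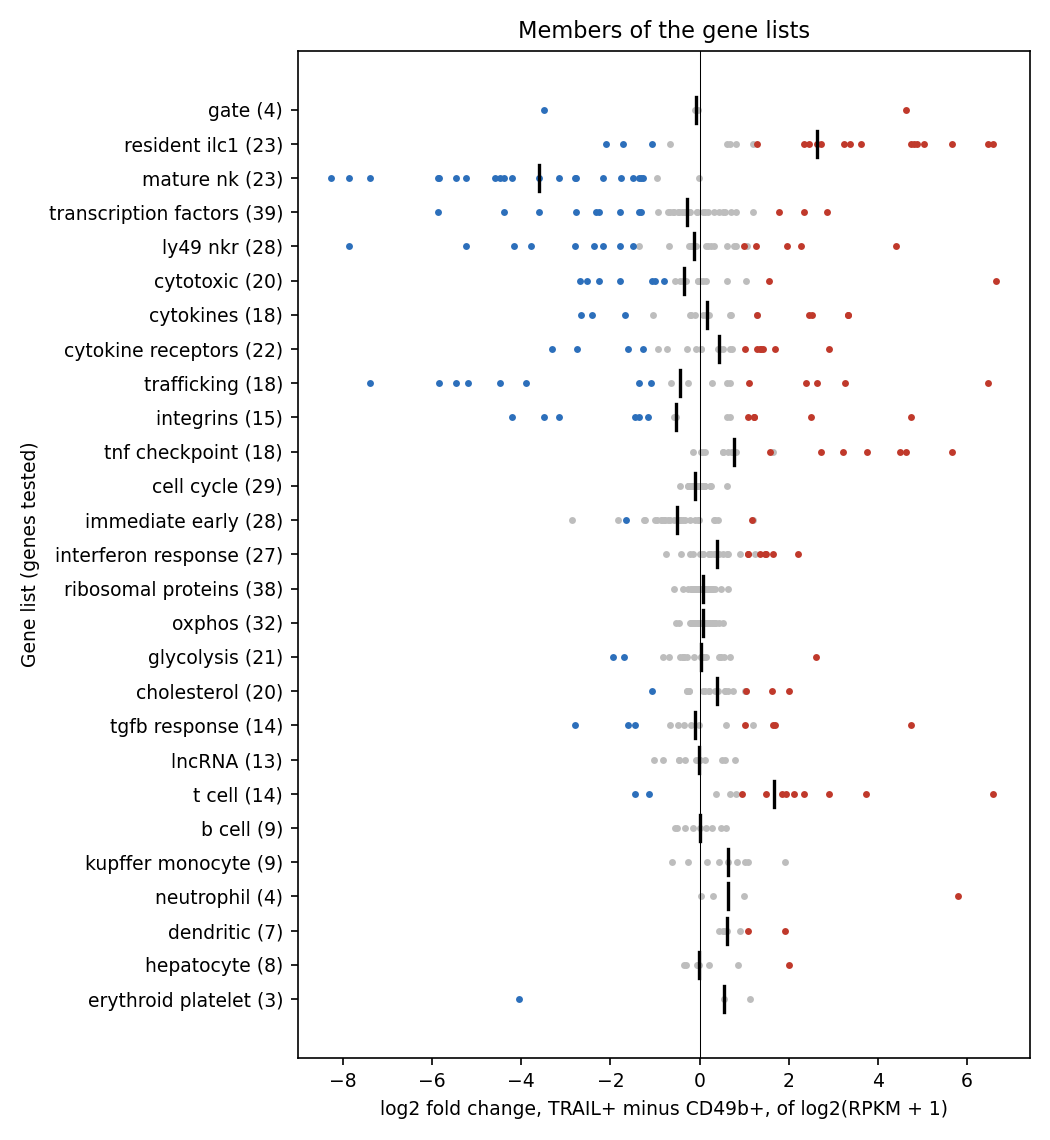
Log2 fold change (TRAIL+ minus CD49b+, of log2(RPKM + 1)) of each tested member of the 27 lists with at least 3 tested genes; red, higher; blue, lower; grey, not past the threshold; black bars, medians. The resident list has a median of 2.63 and the mature NK list of -3.60.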

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

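Changing the pseudocount, the filter, the scaling between libraries or the variance prior kept every count of higher and lower genes within 1.5 times, and the genes shared with the 866 kept their direction in each setting. Shared calls ran from 695 with an RPKM minimum of 5 to 860 with a pseudocount of 0.5 RPKM. No scaling moved the median of all genes beyond 0.1 on the log2 scale. An adjusted p of 0.01 left 230 higher and 193 lower genes, all at least 2-fold. With the replicate number as a block, 1049 genes were higher and 833 lower, 1882 in all, including the 866, and no list call changed. Libraries of the same number deviated together (correlation 0.563 across genes), but 2 pairs and the labels do not establish a pairing. The gene length correction, added after seeing the data, gave 716 higher and 596 lower genes and kept 853 of the 866. Log2 length had a Spearman rho across genes of 0.555 with the difference of the TRAIL+ replicates and 0.338 with that of the CD49b+ replicates, and the correction lowered the SD of these differences from 0.529 to 0.453 and from 0.364 to 0.349. Voom on the recovered reads, also added, gave 491 and 402 and shared 826.

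Leaving out 1 library gave 245 to 777 higher and 198 to 763 lower genes, 245 to 540 and 198 to 586 at 2-fold or more, 5 to 8 lists higher and 4 to 5 lists lower. The low gene counts came without a CD49b+ library and the high ones without TRAIL+ replicate 1. Each such fit has 1 residual degree of freedom and assumes that the lone library varies like the other group. Without a CD49b+ library the spread comes from the TRAIL+ pair alone, which differed more (0.529 against 0.364). With all 4 of these fits 394 of the 866 genes stayed past the threshold, and of 93 named genes past it 69 did. Camera with an estimated correlation called 0 of 27 lists in either direction, against 6 higher and 3 lower. With fry, which does not compare a list with other genes, 4 list calls were lost (transcription factors, cholesterol, dendritic cells and immediate-early genes) and 3 gained (gate, cytokine receptors and trafficking). The cause of these list changes was not tested. The planned count models were not run. At 7.57 to 8.47 reads for 1 RPKM in a gene of 2000 bases, genes near the filter have little power. In the simulation 40% of 2-fold changes were recovered, but only genes with more reads than these were changed.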

Other observations

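The genes in the first 2 paragraphs were named after their values were seen and were not tested as groups, and the tests of the patterns below were chosen after the result was seen, except the length test of the cell markers. Of 27 tested genes of Notch signalling, 7 were higher and 2 lower, where 8.62% of all tested genes were called. Rbpj, the nuclear effector gene of Notch signals, rose 7.80-fold in TRAIL+ cells (44.9 ± 3.69 against 5.76 ± 0.804 RPKM). The ligand genes Dll1 and Jag1 rose 79.2-fold (44.9 to 338 with 1 library left out) and 14.0-fold, and Dtx1 4.56-fold. The other higher genes, Numbl, Psen2 and Dtx3, rose 2.88-fold, 2.04-fold and 1.92-fold. Their calls were lost without either CD49b+ library, and those of Psen2 and Dtx3 also without TRAIL+ replicate 2. Hes1 and Nrarp, which Notch signals induce in many cells, were 6.26-fold (3.97 to 14.8) and 10.1-fold lower. The call of Hes1 was lost without CD49b+ replicate 1 (adjusted p = 0.106) and with voom (0.0521). Cdh1, which encodes E-cadherin, stood at 18.9 ± 3.58 against 0.277 ± 0.0144 RPKM, and Epcam, with 1 read in CD49b+ cells, had a ratio of 299 (exact 95% counting interval 53.2 to 11847). Another cadherin gene, Cdh22, had 0 reads in TRAIL+ cells and was at least 127-fold lower against a floor of 3 reads over the group.

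The feedback genes Cish and Socs2, targets of cytokine signals through STAT5, were 9.15-fold and 13.2-fold higher in TRAIL+ cells, while Socs3 was 4.30-fold lower (3.08 to 7.09 with 1 library left out), a call lost without CD49b+ replicate 1 (adjusted p = 0.0977). Of the regulators of G protein signalling, Rgs1 stood at 472 ± 81.8 against 93.1 ± 23.5 RPKM, and Rgs10 and Rgs18 were 8.18-fold and 5.43-fold higher, as was Rgs3, whose call was lost without either CD49b+ library (adjusted p = 0.154 and 0.103). Rgs16, with 3 reads in TRAIL+ cells, was lower, a ratio of 44.8 (exact 95% counting interval 15.0 to 220). Flna, which encodes filamin A, stood at 66.1 ± 24.7 against 372 ± 86.2 RPKM, the lamin gene Lmna was 22.3-fold lower (14.6 to 47.2) and the actinin gene Actn1 23.0-fold higher. Khdc1c, with 0 reads in TRAIL+ cells, was at least 61.5-fold lower, and its close copies can share reads. S100a4 stood at 1330 ± 404 against 136 ± 33.7 RPKM.

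Cd3g and 8 other genes of the T-cell list were higher in TRAIL+ cells. For Cd3g, T cells in the sort are argued against, since Cd3d and Cd3e, which T cells express beside it, together gained 6.87% of its gain, and at most 8.54% in any pair of a TRAIL+ and a CD49b+ library. Reads from a neighbouring gene are argued against as well, since the highest of 4 neighbours of Cd3g with a row, Cd3d, reached 4.80% of its level in TRAIL+ cells. For the other 17 genes of the list with a row, T cells in the sort and transcription in TRAIL+ cells cannot be told apart. Of these, 8 (47.1%) were called higher and 2 lower. Cd3d (45.0 ± 21.2 against 10.3 ± 0.245 RPKM) and Cd4 (3.84 ± 0.382 against 0.383 ± 0.426) were among the higher ones. Cd5, Cd6, Cd8b1 and Themis showed no gain, with 25 reads together in each group. They were under the minimum for testing and could not be called, so 47.1% understates the share of tested genes. A candidate explanation for Cd3g, held as a hypothesis found on these data, is that TRAIL+ cells themselves transcribe it (936 ± 176 RPKM), and whether all or a part of them do so stays open.

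The immediate-early list was lower in TRAIL+ cells (adjusted p = 0.0178, median log2 fold change -0.52), with an adjusted p = 0.897 with an estimated correlation. A trend with gene length is argued against, since the median was -0.55 after the correction for length. The lower level may come from TRAIL+ replicate 2 alone, whose list sum was 3346 RPKM against 6514 to 7648 in the other libraries, and without it the median was 0.0750 and the adjusted p 0.814, with the test still in the lower direction. What set this library apart, such as the time or temperature of handling, is not recorded in the labels and was not tested, and a biological difference between the subsets stays untested.

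Markers of several other cell types were higher in replicate 1 of both groups. Of 53 markers from 6 lists with at least 1 RPKM in a library, 44 (83.0%) were higher in replicate 1 of both groups. This held for 34.7% of all 10435 such genes, and for most members of each of the 6 lists. The lists were those of B cells, Kupffer cells and monocytes, neutrophils, dendritic cells, hepatocytes, and erythroid cells and platelets. Left out were T cells, other innate lymphoid cells, endothelial and stellate cells, and mast cells and basophils. None of these left-out lists had a higher summed RPKM in replicate 1 of both groups. The 83.0% therefore holds for the chosen lists only. A gene length trend is argued against, since 85.0% of 40 tested markers were in this order after the correction for length. RNA or cells of other types in both replicate 1 libraries may be the source, led by Lyz2 (81.9 and 122 RPKM against 9.21 and 8.87 in replicate 2) and Hbb-b2 (92.3 and 102 against 31.7 and 5.22), although the sort gates and red cell lysis would remove most of them, and no biological explanation was tested. How far it bears on the difference between the subsets stays open. Of the 40 tested markers, 5 passed the threshold between groups (Mmp9, Xcr1, Itgax and Trf higher, Gp1bb lower). Of these, Mmp9 and Gp1bb were higher in replicate 1 of both groups, and Xcr1, Itgax and Trf were not. In TRAIL+ replicates 1 and 2, Mmp9 stood at 111 and 108 RPKM, Xcr1 at 2.98 and 3.20, Itgax at 373 and 309, and Trf at 83.1 and 96.9. Gp1bb stood at 16.9 and 16.1 in the CD49b+ replicates. These steps, within the group where each gene was higher, were far smaller than those of Lyz2. They argue against the replicate 1 source for the high level of these 5 genes in that group. In the CD49b+ replicates, however, Mmp9 stood at 2.70 and 0.0807 RPKM, on 36 and 1 reads. Its low level there may hold replicate 1 signal, which leaves the size of its fold uncertain. The Kupffer, neutrophil and hepatocyte lists did not pass with all 4 libraries (camera adjusted p = 0.253, 0.253 and 0.463, and 0.897 each with an estimated correlation). They moved higher without CD49b+ replicate 1.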
